A study of Mus musculus with 8 samples.

How the data were processed

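The 8 arrays were single-colour Agilent mouse arrays labelled with Cy3 from total RNA, per the labels' protocols, which name a Qiagen RNeasy kit and the standard Agilent labelling. All cells carried the R26-M2rtTA background, and the infected ones the transgenes Nr5a1, Wt1 and Dmrt1. The deposited values are on a log2 scale and range from 4.38 to 19.05, with a median of 6.20 in every column. Sorted columns differ by at most 0.0053, so the arrays share 1 distribution. Per the submitters' processing notes limma was used, without a version. Background correction, normalization settings and detection calls are not given in the sources used here.

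The value table held 62976 features. Gene names came from the probe table supplied with the series and the reference gene table (names of assembly GRCm38.p6, no coordinates used): 31465 features had 1 gene symbol, 0 had several and 31511 were unnamed here and not analysed. Of the named features 29050 were matched through an accession, 2061 through a current symbol, 349 through a synonym and 5 kept an older name, and 3282 symbols were updated. They gave 20738 genes, of which 6171 had 2 or more features, and the feature with the highest mean over all arrays stood for the gene. It was checked that features of 1 gene move together, with a median correlation of 0.85 against 0.01 for random pairs.

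All 8 arrays entered 1 limma model with 4 group means, followed by contrasts, empirical Bayes moderation and Benjamini-Hochberg adjustment within each comparison, two-sided, at an adjusted p under 0.05. Group values are mean ± SD of 2 arrays. SE is the moderated standard error, with a median of 0.11 over genes and with 4 residual and 2.69 prior degrees of freedom. "Rose", "fell", "higher" and "lower" are used for genes that passed this threshold. Changes are log2 differences unless a fold is stated. Nothing in the labels ties an array of 1 group to an array of another beyond the sample codes.

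Gene lists were written from general knowledge before the data were examined, as were the main model, the thresholds and most alternatives. They are Sertoli cell markers, fetal Sertoli genes, adult Sertoli genes, fibroblast and mesenchymal genes, epithelial genes, steroidogenic and Leydig genes, germ cell genes, peritubular myoid and smooth muscle genes, granulosa and ovarian genes, endothelial genes, macrophage genes, mesothelial genes, skeletal muscle genes, cartilage and bone genes, neural genes, cell cycle genes, senescence genes, interferon response genes, sterol synthesis genes, tight and gap junction genes, basement membrane genes, Hox genes, sex chromosome genes and gonadal transcription factors. The 3 introduced genes were left out of every list, and only members with a named feature were counted. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the arrays, adjusted over all 144 list tests. In the second form p-values could be far larger even where the estimated correlation was below 0.01, so a call lost there need not reflect correlation. The fry PValue.Mixed tests whether genes change in either direction; it does not compare with other genes. Its adjusted p was 0.0043 or lower for every list. Counts adjusted over the list alone use Benjamini-Hochberg within the list.

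Named genes followed a rule fixed before the data were examined. It takes the 3 introduced genes, the called genes with the largest change in either direction whose arrays do not overlap between the 2 groups (8 per direction in 3 comparisons, 5 in the others), and from each list up to 4 called members with the largest change and up to 2 uncalled members with the highest level. Clone names and predicted genes were left out. Members named outside this rule, such as Sox9, Amh, Cldn11 against MEF and those moving against the name of their list, were chosen after their values were seen.

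The model was tested on simulated data with the size of the real arrays and 1 moderated spread per gene for all groups. In NWD-MEF 200 changes were planted, and recovery was scored against MEF only. The model recovered 12% of 50 genes at a log2 change of 0.5, 88% at 1, 100% at 2 and 98% at 4. It made 11 false calls and 0 sign errors. The real spread was unequal, with an SD between the 2 arrays of 0.32 in mature Sertoli cells and 0.17 in MEF. Only 200 of 20738 genes were changed there, whereas 41.9% to 64.7% of genes changed in the real comparisons. The adjusted p threshold acts differently at such shares, so these rates need not hold for the real data. For the overlap of changes that share the MEF arrays, 100 draws of unchanged groups gave the covariance to set against the measured one, and 20 simulations gave at most 1 shared call. Analyses used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.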

Results

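To ask how far mouse embryonic fibroblasts carrying Nr5a1, Wt1 and Dmrt1 had moved toward Sertoli cells, 8 single-colour arrays were compared. They covered 4 groups of 2 arrays each: uninfected fibroblasts (MEF), fibroblasts infected with the 3 factors (NWD-MEF), immature Sertoli cells from 19 dpc testes and mature Sertoli cells from 8 week old testes. In total 20738 genes were tested in 6 comparisons with limma at an adjusted p under 0.05. The labels conflict on timing, because the growth protocol gives 1 month of doxycycline for the infected cells and 3 days of culture for the others, whereas most sample descriptions speak of 2 weeks after doxycycline was withdrawn. Whether the factors were switched on at collection is therefore not settled by the labels. The labels also do not say whether the 2 arrays of a group came from separate cultures or animals, so every p-value measures only the spread between these arrays.

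NWD-MEF stood apart from the other 3 groups, and immature Sertoli cells were the group nearest to MEF. The first component held 44.8% of the variance and placed the NWD-MEF arrays at 149.9 and 151, against -32 to -79.5 for all others. A second component with 39.1% ran from MEF at -96.4 and -97.8 to mature Sertoli cells at 134.1 and 107.6. Averaged over the 4 array pairs of 2 groups, the correlation was 0.961 between MEF and immature Sertoli cells and 0.925 between immature and mature Sertoli cells. For NWD-MEF it was 0.904 with MEF, 0.91 with immature and 0.888 with mature Sertoli cells. Replicate arrays correlated at 0.9979 in MEF, 0.9979 in NWD-MEF, 0.9967 in immature and 0.9916 in mature Sertoli cells. The mature pair was the most variable, with an SD of the difference of 0.46 against 0.23 in MEF.

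**Figure D1:**
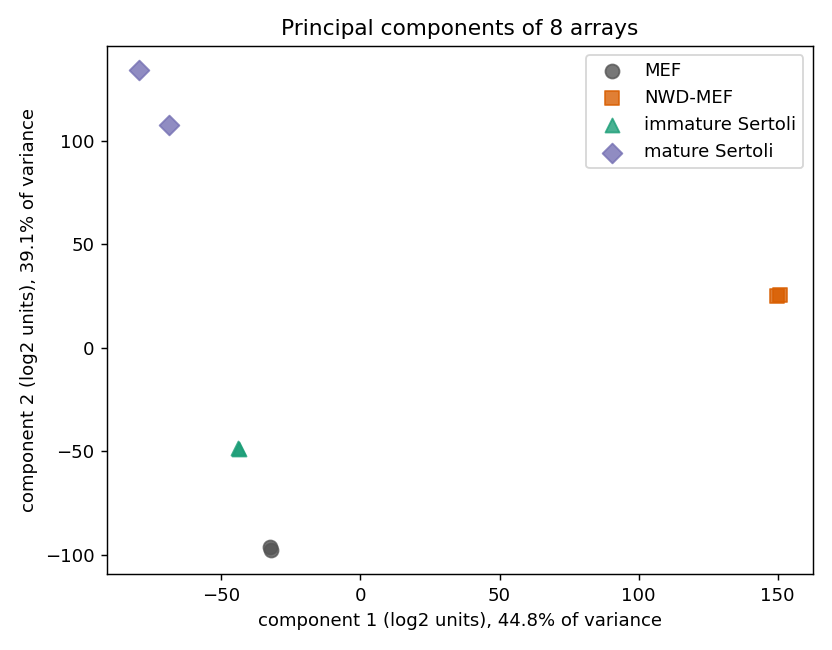
First component (horizontal, 44.8% of variance) against second component (vertical, 39.1%) of log2 intensity over all tested genes, in log2 units. Each point is 1 array, with colour and marker giving the group.

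The first question was whether transcripts of the 3 introduced factors were raised in NWD-MEF. None of them rose. Nr5a1, a nuclear receptor of the gonads and adrenals, fell by 0.93 (SE 0.10, limma adjusted p = 0.00014) from 8.39 ± 0.13 in MEF to 7.46 ± 0.07 in NWD-MEF. Wt1, a zinc finger factor of the early gonad, fell by 2.21 (SE 0.09, adjusted p = 1.37e-06) from 12.32 ± 0.05 to 10.12 ± 0.01. Dmrt1, a male sex determination factor, read 8.19 ± 0.19 in MEF and 8.60 ± 0.01 in NWD-MEF, a difference of 0.41 that was not called (SE 0.16, adjusted p = 0.0656). Its call was gained in 6 of the alternative settings, at adjusted p from 0.011 to 0.037. Each factor was read by 1 array feature, whose place in the transcript is not given in the sources used here, so whether the introduced copies were read is unknown.

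All 3 factors were high in the Sertoli groups. Nr5a1 exceeded MEF by 5.20 in immature and 5.49 in mature Sertoli cells (SE 0.10 for each), Wt1 by 3.10 and 4.32 (SE 0.09), and Dmrt1 by 1.60 and 2.70 (SE 0.16, adjusted p = 0.000245 and 9.14e-06). NWD-MEF lay below immature Sertoli cells by 6.12 for Nr5a1, 5.30 for Wt1 and 1.19 for Dmrt1, and below mature ones by 6.42, 6.53 and 2.28. From immature to mature cells Wt1 rose by 1.23 (adjusted p = 3.63e-05) and Dmrt1 by 1.10 (adjusted p = 0.000916). Nr5a1 was 0.29 higher in mature cells (adjusted p = 0.0344), and that call was lost in 7 alternative settings, at adjusted p from 0.052 to 0.16.

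**Figure D2:**
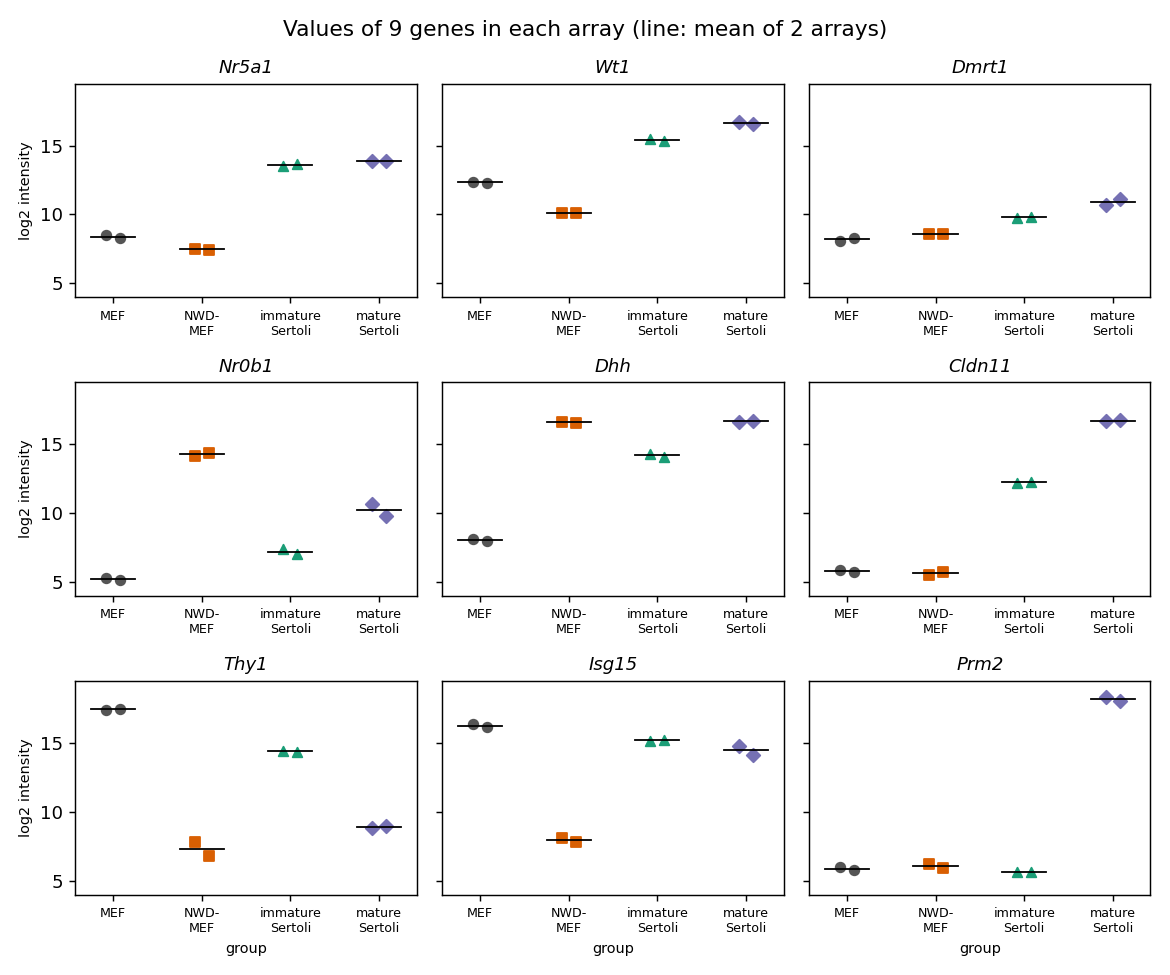
Log2 intensity (vertical) of Nr5a1, Wt1, Dmrt1, Nr0b1, Dhh, Cldn11, Thy1, Isg15 and Prm2 in the 4 groups (horizontal). Each point is 1 array and each line the mean of 2 arrays, such as 16.6 for Dhh in NWD-MEF.

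How the infected cultures differed from uninfected ones was asked by comparing NWD-MEF with MEF. By the growth protocol they also differ in time, with 1 month of doxycycline against 3 days of culture, and no matched uninfected arm exists. The differences below are those of the cultures and need not be effects of the factors. Several Sertoli genes rose steeply, among them Nr0b1 and Dhh, while 28 of 29 fibroblast, 11 of 12 smooth muscle and 20 of 22 interferon response genes fell one by one. Nr0b1, an orphan nuclear receptor of the steroidogenic and Sertoli lineages, went from 5.21 ± 0.12 to 14.29 ± 0.13, a rise of 9.08 (SE 0.29, adjusted p = 3.3e-07). Its MEF value lies under 5.67, the 40th percentile of all values, so the size of this rise is not exact. Dhh, the hedgehog ligand that Sertoli cells secrete, went from 8.05 ± 0.06 to 16.60 ± 0.04, a rise of 8.55 (SE 0.09, adjusted p = 1.6e-08) or 376-fold. In all, 11388 genes changed (54.9%), with 6221 higher and 5167 lower, but cyclic loess scaling moved the share of changed genes that were higher from 54.6% to 47.1% and quantile scaling to 58.1%. Changes of 16-fold or more were mostly losses, with 198 genes higher and 630 lower.

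Other genes with the largest rises were Vpreb3, a surrogate light chain gene of pre-B cells, at 8.98, the proton pump subunit Atp6v1c2 at 8.69, the alcohol dehydrogenase Adh4 at 8.20, the chloride channel gene Clic5 at 8.11, Akr1cl at 7.83 and the glutathione transferase Gstm7 at 7.81 (SE 0.08 to 0.29 with Nr0b1). The largest fall was that of Meg3, an imprinted noncoding RNA, by 10.46 (SE 0.31, adjusted p = 2.5e-07). Lrrc17 fell by 10.19, the surface antigen Thy1 by 10.13, the growth factor Ptn by 10.10, the protease Prss23 by 9.91, the matrix gene Fbln2 by 9.88, Serpinf1 by 9.87 and the chemokine Cxcl12 by 9.80 (SE 0.24 to 0.37). In every comparison the sizes and ranks of rises from the lowest values, and of falls to them, depend on how background was removed from the dimmest features, a step not given in the sources used here. The 2 NWD-MEF arrays differed in these 8 genes, all of them higher in array 1, with Thy1 at 7.33 ± 0.72 (7.83 and 6.82) against 17.46 ± 0.03 in MEF.

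Sertoli cell markers moved up in part only. Of 32 measured, 17 rose, 8 fell and 7 were not called (25 called adjusted over the list alone), with a median of 0.40 and a mean of 1.73. Camera called the list at adjusted p = 0.027, with adjusted p = 0.19 with an estimated correlation. The call was also lost without mature replicate 1 (adjusted p = 0.055) or 2 (0.053) and with the mean over all features of a gene (0.056). Scaling moved the median to 0.23 (cyclic loess) and 0.63 (quantile). Beside Nr0b1 and Dhh, the largest rises were Etd at 6.68 (SE 0.10) and the transcription factor Gata1 at 6.41 (SE 0.16). Sox9, the main driver of Sertoli fate, rose by 2.58 (SE 0.09). Against the name of the list, Fgf9 fell by 3.74, Trf by 3.40, Inhbb by 2.69, Rhox5 by 2.62, Aard by 2.22, Hsd17b1 by 1.52, Gata4 by 1.17 and Sox8 by 0.37. Rhox8 (0.19) and Gdnf (0.03) were not called, and neither were Amh (0.13), the hormone of the fetal testis, nor Cldn11 (-0.18), the claudin of Sertoli tight junctions.

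Neither stage of Sertoli genes was called as a list. Among 16 fetal Sertoli genes 9 rose, 6 fell and 1 was not called (15 called adjusted over the list alone), with a median of 0.40 and adjusted p = 0.27; the keratin Krt18 fell by 7.59 (SE 0.21). Of 17 adult Sertoli genes 7 rose, 4 fell and 6 were not called (11 called adjusted over the list alone), with a median of 0.11 and adjusted p = 0.22. Ocln, a tight junction protein, rose by 7.11 (SE 0.14), the actin bundler Espn by 4.81 (SE 0.09) and Shbg, which encodes a sex steroid carrier, by 4.33 (SE 0.12). Among 16 tight and gap junction genes 7 rose, 4 fell and 5 were not called (11 called adjusted over the list alone; median 0.16, adjusted p = 0.27). Cdh2, or N-cadherin, fell by 8.53 (SE 0.13), Cgn rose by 4.27 and F11r by 3.44, and Cldn12 (0.15) and Nectin3 (0.17) were not called.

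Lists with mostly lower members came next. Of 29 fibroblast and mesenchymal genes 28 fell and 1 rose (29 called adjusted over the list alone), with a median of -7.66 (camera adjusted p = 1.9e-16; adjusted p = 0.16 with an estimated correlation). Beside Thy1 and Fbln2, the matrix gene Postn fell by 9.72 (SE 0.24) and the collagen gene Col3a1 by 9.5 (SE 0.31). Zeb2, a factor of mesenchymal cells, rose by 1.07. Among 12 peritubular myoid and smooth muscle genes 11 fell and 1 was not called (11 called adjusted over the list alone), with a median of -3.91 and adjusted p = 4.8e-07 (adjusted p = 0.096 with an estimated correlation). Actg2 fell by 9.74, the actin regulator Cnn1 by 7.33, Myl9 by 5.08 and Acta2 by 4.86 (SE 0.08 to 0.25), and Smtn (0.22) was not called. Interferon response genes fell as a group, with 20 of 22 lower and 2 not called (20 called adjusted over the list alone), a median of -4.76 and adjusted p = 9.1e-10 (adjusted p = 0.27 with an estimated correlation). Isg15, a ubiquitin-like protein, fell by 8.30 (SE 0.22), Ifi44 by 7.81, Oas1a by 7.56 and Oasl2 by 7.32, whereas Gbp3 (-0.49) and Rsad2 (0.35) were not called.

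**Figure D3:**
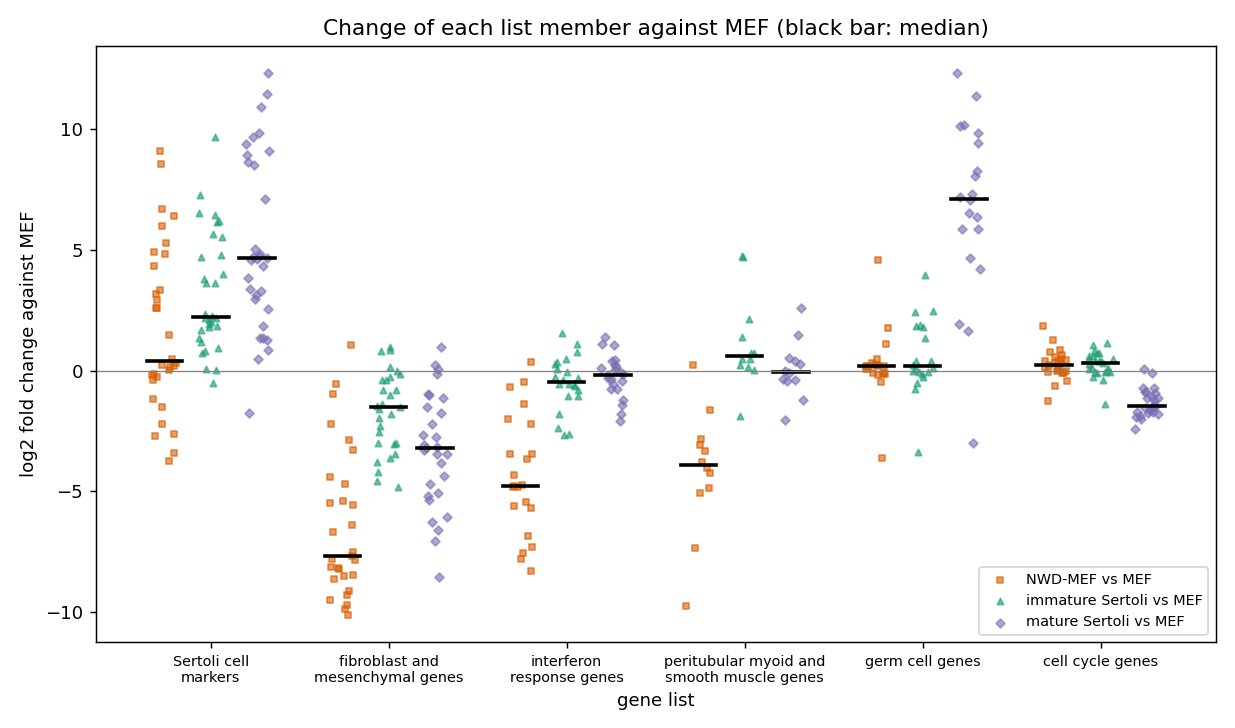
Log2 fold change against MEF (vertical) of each member of 6 gene lists, in NWD-MEF, immature and mature Sertoli cells (horizontal). Each point is 1 gene and each black bar the list median, such as -7.66 for fibroblast and mesenchymal genes in NWD-MEF.

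Many markers of other lineages were also lower. Whether the MEF cultures held other cells that NWD-MEF lacked was not tested. Macrophage genes had 14 of 16 lower and 2 higher (16 called adjusted over the list alone), with a median of -1.73 and adjusted p = 0.00013 (adjusted p = 0.27 with an estimated correlation). Tyrobp, a signalling adaptor of myeloid cells, fell by 4.81, C1qc fell by 4.26, C1qa by 3.82 and Lyz2 by 2.37 (SE 0.13 to 0.18), and Csf1r rose by 1.12 and Fcgr3 by 0.60. Mesothelial genes had 7 of 10 lower, 1 higher and 2 not called (8 called adjusted over the list alone; median -3.56, adjusted p = 0.00092, and adjusted p = 0.23 with an estimated correlation). The uroplakins Upk1b and Upk3b fell by 4.78 and 4.42, and Rspo1, a secreted WNT agonist, rose by 0.77. Skeletal muscle genes had 7 of 12 lower, 1 higher and 4 not called (8 called adjusted over the list alone; median -1.19, adjusted p = 0.009, and adjusted p = 0.19 with an estimated correlation), in which Acta1 fell by 6.21 and Actc1 fell by 4.4. Cartilage and bone genes had 8 of 12 lower and 4 not called (8 called adjusted over the list alone; median -1.27, adjusted p = 0.0043, and adjusted p = 0.19 with an estimated correlation). Col2a1, the main cartilage collagen, fell by 9.12 (SE 0.54) and Col11a1 by 8.09 (SE 0.23).

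Hox, senescence and gonadal factor genes were mostly lower as well. Hox genes had 25 of 38 lower, 6 higher and 7 not called (32 called adjusted over the list alone; median -1.29, adjusted p = 0.00017, and adjusted p = 0.28 with an estimated correlation). Hoxb2 fell by 3.78, Hoxc5 fell by 3.72 and Hoxc6 by 3.45, but the posterior gene Hoxb13 rose by 6.87 (SE 0.12), and Hoxb9 (0.38) and Hoxb4 (0.15) were not called. Senescence genes had 9 of 11 lower, 1 higher and 1 not called (11 called adjusted over the list alone; median -2.37, adjusted p = 0.00034, and adjusted p = 0.20 with an estimated correlation). Igfbp5 fell by 8.66, the cytokine Il6 by 6.73, Igfbp3 by 4.79 and Mmp3 by 4.18 (SE 0.10 to 0.23), whereas Cdkn2a, a cell cycle inhibitor locus, rose by 0.97. Of 18 gonadal transcription factors 12 fell, 2 rose and 4 were not called (14 called adjusted over the list alone; median -0.65, adjusted p = 0.0042, and adjusted p = 0.17 with an estimated correlation). Beside the rise of Nr0b1, Emx2 fell by 4.04, Lhx9 by 3.88 and Nr2f2 fell by 3.41 (SE 0.09 to 0.14).

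Smaller shifts came from 3 further lists. Sterol synthesis genes had 11 of 15 lower, 2 higher and 2 not called (15 called adjusted over the list alone; median -0.65, adjusted p = 0.011, and adjusted p = 0.53 with an estimated correlation). Sqle fell by 2.45 and Cyp51 by 1.91, but Hsd17b7 rose by 2.41 and Dhcr7 by 1.81. Basement membrane genes had 9 of 18 lower, 4 higher and 5 not called (13 called adjusted over the list alone; median -0.29, adjusted p = 0.032, and adjusted p = 0.26 with an estimated correlation). Nid1 fell by 9.77, Lama1 by 7.21 and Nid2 by 7.03 (SE 0.14 to 0.16). Granulosa and ovarian genes had 5 of 11 lower, 2 higher and 4 not called (9 called adjusted over the list alone; median -0.33, adjusted p = 0.033, and adjusted p = 0.20 with an estimated correlation). Inhba, an activin subunit, fell by 7.65, Fst by 6.60 and Wnt4 by 3.68, and the ovarian factor Foxl2 (-0.15) was not called. The calls of these last 2 lists were lost without dim genes (0.050 and 0.051) and without either mature array (0.051 to 0.055).

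The remaining lists were not called against MEF. Steroidogenic and Leydig genes had 7 of 13 higher, 4 lower and 2 not called (12 called adjusted over the list alone; median 0.46, adjusted p = 0.16). The lipoprotein receptor Scarb1 rose by 4.37, Fdx1 by 4.15, the side-chain cleavage enzyme Cyp11a1 by 3.69 and Star by 2.21 (SE 0.09 to 0.19), Hsd3b1 fell by 2.12, and Por (0.22) was not called. Epithelial genes differed in sign between median (0.05), mean (-0.37) and test (up, adjusted p = 0.75), with 9 of 25 higher, 6 lower and 10 not called (15 called adjusted over the list alone). The cadherin Cdh3 fell by 6.79 and the keratin Krt19 by 6.37. Germ cell genes had 3 of 20 higher, 1 lower and 16 not called (4 called adjusted over the list alone; median 0.19, adjusted p = 0.55), with the germline helicase Ddx4 up by 4.59 and Gfra1 down by 3.60. Cell cycle genes had 11 of 25 higher, 3 lower and 11 not called (14 called adjusted over the list alone; median 0.25, adjusted p = 0.19), with Bub1b up by 1.84, Kif11 up by 1.27 and Ccne1 down by 1.26.

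Neural genes had 4 of 12 higher, 5 lower and 3 not called (9 called adjusted over the list alone; median -0.14, adjusted p = 0.50). Ncam1 fell by 7.26, Stmn2 by 6.62 and the tubulin Tubb3 by 6.53, and the neurofilament gene Nefl rose by 6.95 (SE 0.07 to 0.15). Endothelial genes had 2 of 14 higher, 7 lower and 5 not called (10 called adjusted over the list alone; median -0.23, adjusted p = 0.23), with Esam down by 1.61, Emcn down by 1.35 and Egfl7 up by 0.88. Sex chromosome genes had 2 of 7 lower and 5 not called (2 called adjusted over the list alone; median -0.08, adjusted p = 0.17). The Y-linked translation factor Eif2s3y fell by 5.40 (SE 0.10) from 10.52 to 5.12, Uty fell by 0.61, and Xist (-0.08) and Zfy2 (0.01) were not called. Over all 6 comparisons 76 of 144 list tests were called, and only 2 calls hold with an estimated correlation, both for Sertoli cell markers against MEF.

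To describe what sets fetal Sertoli cells apart from fibroblasts, immature Sertoli cells were compared with MEF. Of the listed genes, 28 of 32 Sertoli cell markers and 8 of 13 steroidogenic genes rose one by one, while 30 of 38 Hox and 21 of 29 fibroblast genes fell. Cst12, a cystatin of the male reproductive tract, rose by 9.69 (SE 0.09, adjusted p = 6.5e-08) from 5.13 ± 0.03 to 14.82 ± 0.05, a size that is not exact because the MEF value lies under the 40th percentile of all values (5.67). Altogether 8687 genes changed (41.9%), 4099 higher and 4588 lower, the fewest of the 6 comparisons. Cyclic loess moved the higher share from 47.2% to 50.9% and quantile scaling to 47.4%. Other large rises were Cstdc1 at 8.55, the lipid droplet gene Cidea at 8.33, the muscle genes Pdlim3 at 8.28, Casq2 at 8.18 and Mybpc3 at 7.40, Misp3 at 7.33 and the prostaglandin D synthase Ptgds at 7.28 (SE 0.09 to 0.19). Col2a1 fell by 9.63 (SE 0.54, adjusted p = 1.4e-05), the retinoid-binding gene Crabp1 by 8.01, Zic1 by 7.85, the connexin Gjb2 by 7.62, Igfbp5 by 7.31, the BMP antagonist Grem1 by 7.08, Lrrc15 by 6.98 and Irx1 by 6.90 (SE 0.11 to 0.17 after Col2a1).

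Of 32 Sertoli cell markers 28 rose, 1 fell and 3 were not called (30 called adjusted over the list alone), with a median of 2.22 and adjusted p = 1.1e-17, a call that holds at adjusted p = 0.045 with an estimated correlation. After Cst12 and Ptgds, Defb19 rose by 6.51 and Cldn11 by 6.43 (SE 0.11 and 0.09), Rhox5 fell by 0.52, and Gdnf (0.08) and Hsd17b1 (0.82) were not called. Among 16 fetal Sertoli genes 13 rose and 3 were not called (14 called adjusted over the list alone; median 2.18, adjusted p = 5.7e-10, and adjusted p = 0.073 with an estimated correlation), with Cst9 at 6.20, Dhh at 6.16 and Aard at 5.53. Adult Sertoli genes had 11 of 17 higher, 2 lower and 4 not called (13 called adjusted over the list alone; median 1.82, adjusted p = 1.4e-05, and adjusted p = 0.096 with an estimated correlation), and Shbg rose by 5.64. Tight and gap junction genes had 11 of 16 higher, 2 lower and 3 not called (13 called adjusted over the list alone; median 1.32, adjusted p = 2.3e-05, and adjusted p = 0.16 with an estimated correlation). Cgn rose by 4.90, Jam2 by 3.64 and Ocln by 3.12, and Jam3 (0.14) was not called. Of 18 gonadal transcription factors 10 rose, 4 fell and 4 were not called (14 called adjusted over the list alone; median 0.48, adjusted p = 0.031, and adjusted p = 0.20 with an estimated correlation), led by Tcf21 at 6.56 and Gata4 at 4.80, with Six4 down by 2.90.

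Beside the Sertoli markers, some genes of other testis cells rose, some fell and others were not called. Endothelial genes had 6 of 14 higher, 3 lower and 5 not called (9 called adjusted over the list alone), with camera adjusted p = 0.10. Macrophage genes had 3 of 16 higher, 4 lower and 9 not called (7 called adjusted over the list alone), with camera adjusted p = 0.59. Peritubular myoid and smooth muscle genes had 6 of 12 higher, 1 lower and 5 not called (9 called adjusted over the list alone; median 0.61, adjusted p = 0.0021, and adjusted p = 0.19 with an estimated correlation). The myosin kinase Mylk rose by 4.75 and the smooth muscle myosin Myh11 by 4.70 to 14.58, Synpo2 fell by 1.88, and Tagln (0.15) and Acta2 (0.04) were not called. Steroidogenic and Leydig genes had 8 of 13 higher, 2 lower and 3 not called (10 called adjusted over the list alone; median 1.08, adjusted p = 0.0015, and adjusted p = 0.16 with an estimated correlation). Cyp11a1 rose by 5.95, Hsd3b1 by 4.75 and Hsd17b3 by 4.14 (SE 0.09 to 0.13). Germ cell genes were not called (7 of 20 higher, 3 lower, 10 not called, 10 called adjusted over the list alone; median 0.18, adjusted p = 0.094), though Tex14, a gene of germ cell bridges, rose by 3.97 and Stra8, which germ cells need for meiosis, by 2.41. Sterol synthesis genes had 13 of 15 higher and 2 not called (13 called adjusted over the list alone; median 0.60, adjusted p = 0.00016, and adjusted p = 0.39 with an estimated correlation), with Idi1 at 1.09 and Msmo1 at 0.87.

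Fibroblast and mesenchymal genes fell less uniformly than in NWD-MEF, with 21 of 29 lower, 3 higher and 5 not called (25 called adjusted over the list alone; median -1.52, adjusted p = 1.8e-07, and adjusted p = 0.20 with an estimated correlation). Lum fell by 4.84, S100a4 by 4.57, Twist2 by 4.21 and Fap by 3.80 (SE 0.07 to 0.26), Dcn rose by 0.99, Pdgfra by 0.84 and Zeb2 by 0.81, and Vim (-0.15) and Col1a1 (-0.26) were not called. Of 38 Hox genes 30 fell, 5 rose and 3 were not called (35 called adjusted over the list alone; median -1.62, adjusted p = 3.4e-08, and adjusted p = 0.20 with an estimated correlation). Hoxd13 fell by 5.31, Hoxa5 by 4.54 and Hoxa3 by 4.39, whereas Hoxd9 rose by 3.59 and Hoxd8 by 2.42. Senescence genes had 8 of 11 lower, 2 higher and 1 not called (10 called adjusted over the list alone; median -2.09, adjusted p = 0.00092, and adjusted p = 0.20 with an estimated correlation), with Cdkn2a down by 5.62, Il6 by 5.00 and Cdkn2b by 4.13. Interferon response genes were not called (9 of 22 lower, 5 higher, 8 not called, 15 called adjusted over the list alone; median -0.47, adjusted p = 0.16). Median, mean and test differed in sign for skeletal muscle genes (0.00, 0.74, up, adjusted p = 0.52) and sex chromosome genes (0.15, -0.01, up, adjusted p = 0.27).

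For adult Sertoli cells the same question was put to mature Sertoli cells against MEF. RNA of other cells in the mature cultures may contribute to these differences, as germ cell and macrophage genes also rose. One by one, 31 of 32 Sertoli cell markers, 19 of 20 germ cell and 14 of 16 macrophage genes rose, while 23 of 25 cell cycle, 27 of 38 Hox and 25 of 29 fibroblast genes fell. The defensin Defb36 rose by 12.38 (SE 0.09, adjusted p = 1.2e-08) from 5.43 ± 0.13 to 17.81 ± 0.09, again a size that is not exact because the MEF value lies under 5.67. The sperm protamine gene Prm2 rose by 12.32 (SE 0.14) to 18.20 ± 0.19, Cst12 by 12.32, Cstdc1 by 12.08 and Defb19 by 11.45. Ptn fell by 10.51 (SE 0.30, adjusted p = 3.1e-07), Lrrc15 by 10.44, the imprinted noncoding RNA H19 by 10.31, Lrrc17 by 9.48 and Igfbp5 by 8.74. Altogether 12858 genes changed (62.0%), 5810 higher and 7048 lower, and 619 were higher by 16-fold or more against 177 lower. With cyclic loess the higher share moved from 45.2% to 51.0%, and with quantile scaling to 39.5%.

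Of 32 Sertoli cell markers 31 rose and 1 fell (32 called adjusted over the list alone; median 4.66, adjusted p = 1.7e-16), a call that holds at adjusted p = 0.045 with an estimated correlation. Cldn11 rose by 10.92 and Cst9 by 9.85 (SE 0.09 and 0.14), whereas Fgf9 fell by 1.74. Adult Sertoli genes had 16 of 17 higher and 1 lower (17 called adjusted over the list alone; median 3.29, adjusted p = 4.2e-09, and adjusted p = 0.073 with an estimated correlation), with Gata1 up by 9.69 and the connexin Gja1 down by 2.67. Fetal Sertoli genes had 13 of 16 higher, 2 lower and 1 not called (15 called adjusted over the list alone; median 3.97, adjusted p = 2.2e-06, and adjusted p = 0.089 with an estimated correlation), among them Aard at 9.38, Ptgds at 9.09 and Dhh at 8.62. Tight and gap junction genes had 12 of 16 higher, 2 lower and 2 not called (14 called adjusted over the list alone; median 1.72, adjusted p = 6.8e-05, and adjusted p = 0.17 with an estimated correlation), with Cgn at 7.94, Jam2 at 6.12 and F11r at 4.15, and Tjp1 (0.04) not called.

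Germ cell genes had the largest list median. Of 20 germ cell genes 19 rose and 1 fell (20 called adjusted over the list alone; median 7.12, adjusted p = 2.8e-10, and adjusted p = 0.20 with an estimated correlation), with Prm1 at 11.36, Smcp at 10.18 and Ldhc at 10.11 (SE 0.17 to 0.58) and Gfra1 down by 3.01. Macrophage genes had 14 of 16 higher, 1 lower and 1 not called (15 called adjusted over the list alone; median 1.88, adjusted p = 2.1e-05, and adjusted p = 0.23 with an estimated correlation). Mrc1 rose by 3.90, Fcer1g by 3.21, Lyz2 by 3.05 and Tyrobp by 3.01, Itgam fell by 1.5, and Ptprc (0.42) was not called. Cell cycle genes had 23 of 25 lower and 2 not called (23 called adjusted over the list alone; median -1.46, adjusted p = 2.1e-07, and adjusted p = 0.19 with an estimated correlation), with Ccne1 down by 2.41, Kif11 by 1.99 and Mcm2 by 1.92. Fibroblast and mesenchymal genes had 25 of 29 lower, 1 higher and 3 not called (26 called adjusted over the list alone; median -3.19, adjusted p = 7.6e-09, and adjusted p = 0.19 with an estimated correlation). Thy1 fell by 8.55, Lum by 7.07 and Mmp2 by 6.58, Zeb2 rose by 0.96, and Vim (0.06) and Dcn (0.22) were not called. Hox genes had 27 of 38 lower, 4 higher and 7 not called (31 called adjusted over the list alone; median -2.38, adjusted p = 6.2e-06, and adjusted p = 0.23 with an estimated correlation), led by Hoxa10 at -4.77 and Hoxa7 at -4.57. Median, mean and test differed in sign for smooth muscle genes (-0.07, 0.06, up, adjusted p = 0.87) and basement membrane genes (-0.08, 0.49, up, adjusted p = 0.86).

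To ask whether NWD-MEF moved in the Sertoli direction over all genes, their changes from MEF were set beside those of the Sertoli cells. Of the 4099 genes higher in immature Sertoli cells 2011 rose in NWD-MEF (49.1%, 1230 expected from the margins), 1028 fell (25.1%, 1021 expected) and 1060 were not called. Of the 4588 lower genes 2405 fell (52.4%, 1143 expected), 1120 rose (24.4%, 1376 expected) and 1063 were not called. Among the 5810 genes higher in mature Sertoli cells 2724 rose (46.9%, 1743 expected), 962 fell (16.6%, 1448 expected) and 2124 were not called. Among the 7048 lower ones 3243 fell (46.0%, 1756 expected), 1594 rose (22.6%, 2114 expected) and 2211 were not called. Dhh, Nr0b1 and Gata1 are examples that rose in NWD-MEF and in mature Sertoli cells, and Thy1, Ptn and Lrrc17 examples that fell in both.

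The covariance of the changes was 0.56 with immature and 1.04 with mature Sertoli cells (r = 0.36 and 0.42). The same MEF arrays enter every difference, and 100 simulated sets of unchanged groups gave a median covariance of 0.025 and a highest of 0.032, leaving 0.54 and 1.02. The simulated r was 0.50, so covariances are compared and not r. With 1 MEF array as control of NWD-MEF and the other of the Sertoli cells, a test chosen after these values were seen, the covariance was 0.55 in both arrangements with immature and 1.02 and 1.03 with mature Sertoli cells. Under that split 1436 and 1427 genes rose in NWD-MEF among those higher in immature cells (807 and 801 expected), and 2184 and 2196 among those higher in mature cells (1280 and 1279 expected). The labels do not say whether the 2 MEF arrays came from separate cultures, so the split removes the shared arrays but not a shared culture. Neither the draws nor the split remove genes whose level is particular to MEF, which would move alike in any other cell type. No unrelated cell type was measured, so the shared movement cannot be assigned to the Sertoli direction in particular.

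How far NWD-MEF remained from fetal Sertoli cells was asked by comparing them with immature Sertoli cells. RNA of other cells in the immature cultures was not tested and may contribute. Against MEF, 6 of 12 smooth muscle and 8 of 13 steroidogenic genes were higher there, and 1 and 2 were lower. Tested one by one, 22 of 32 Sertoli cell markers were lower in NWD-MEF, as were 12 of 12 smooth muscle, 28 of 29 fibroblast and 21 of 22 interferon response genes, but Nr0b1 and Dhh were higher. The muscle gene Pdlim3 was lower by 11.19 (SE 0.10, adjusted p = 1.8e-08; 5.69 against 16.87), the imprinted gene Dlk1 by 10.72, Crispld2 by 10.64, Actg2 by 10.47 and Plac8 by 10.11. The killer cell lectin receptor gene Klra4 was higher by 9.09 (SE 0.35, adjusted p = 8.9e-07; 15.69 against 6.59), the proteoglycan gene Srgn by 8.94, Klra16 by 8.43, Atp6v1c2 by 8.32 and Rundc3a by 8.29. In this comparison 11768 genes changed (56.7%), 6539 higher and 5229 lower in NWD-MEF, although under cyclic loess the higher share moved from 55.6% to 46.4%, and under quantile scaling to 59.5%. By 16-fold or more 611 were lower against 141 higher.

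Of 32 Sertoli cell markers 22 were lower, 8 higher and 2 not called (30 called adjusted over the list alone; median -1.73, adjusted p = 0.00027, and adjusted p = 0.11 with an estimated correlation). Aard was lower by 7.75, Cldn11 by 6.61 and Cst12 by 6.54, and Gdnf (-0.04) and Tsx (-0.16) were not called. Against that direction Nr0b1 was higher by 7.07, Gata1 by 4.59, Etd by 4.50, Vnn1 by 4.04, Espn by 2.99, Dhh by 2.40, Sox9 by 0.88 and Inha by 0.59. Fetal Sertoli genes had 11 of 16 lower and 5 higher (16 called adjusted over the list alone; median -2.23, adjusted p = 0.019, and adjusted p = 0.19 with an estimated correlation), with Krt18 lower by 7.99. Gonadal transcription factors had 10 of 18 lower, 4 higher and 4 not called (14 called adjusted over the list alone; median -0.72, adjusted p = 0.014, and adjusted p = 0.19 with an estimated correlation), with Tcf21 lower by 8.30, Gata4 by 5.97 and Lhx9 by 5.63.

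All 12 smooth muscle genes were lower in NWD-MEF (12 called adjusted over the list alone; median -4.92, adjusted p = 9.1e-09, and adjusted p = 0.089 with an estimated correlation), Myh11 by 8.72 and Mylk by 8.55. Fibroblast and mesenchymal genes had 28 of 29 lower and Zeb2 (0.26) not called (28 called adjusted over the list alone; median -4.68, adjusted p = 2.5e-15, and adjusted p = 0.16 with an estimated correlation), with Col3a1 lower by 9.49 and the proteoglycan Dcn by 9.20. Interferon response genes had 21 of 22 lower (21 called adjusted over the list alone; median -4.03, adjusted p = 1.6e-09, and adjusted p = 0.27 with an estimated correlation), Oasl2 by 7.36 and Isg15 by 7.23, and Rsad2 (0.75) was not called. Basement membrane genes had 14 of 18 lower, 3 higher and 1 not called (18 called adjusted over the list alone; median -1.87, adjusted p = 9.7e-05, and adjusted p = 0.17 with an estimated correlation), with Nid1 lower by 9.52 and Lama1 by 8.64. Sterol synthesis genes had 13 of 15 lower and 2 higher (15 called adjusted over the list alone; median -1.37, adjusted p = 0.00035, and adjusted p = 0.40 with an estimated correlation), with Sqle lower by 2.99 and Hsd17b7 higher by 2.07. Macrophage genes had 12 of 16 lower, 2 higher and 2 not called (14 called adjusted over the list alone; median -1.87, adjusted p = 0.00016, and adjusted p = 0.27 with an estimated correlation), led by Tyrobp at -5.33. Hox genes were not called (19 of 38 higher, 12 lower, 7 not called, 31 called adjusted over the list alone; median 0.98, adjusted p = 0.23), with Hoxb13 higher by 8.10, Hoxa7 by 5.43 and Hoxd9 lower by 4.62. The cell cycle list differed in sign between median (-0.09) and mean (0.00; down, adjusted p = 0.50).

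Distance from adult Sertoli cells was asked by comparing NWD-MEF with mature Sertoli cells. Germ cell and macrophage genes were also higher in the mature cultures than in MEF, so RNA of other cells may contribute to these differences. Dhh did not differ by the test, while 28 of 32 Sertoli cell markers and 19 of 20 germ cell genes were lower in NWD-MEF and 22 of 25 cell cycle genes were higher, each tested singly. The difference in Dhh was -0.06 (SE 0.09, not called), with 16.60 in NWD-MEF. Prm2 was lower by 12.13 (SE 0.14), Aard by 11.60 (SE 0.10), Cstdc1 by 11.52, Wfdc18 by 11.20 and Cldn11 by 11.10 (SE 0.09, adjusted p = 1.1e-08; 5.62 ± 0.13 against 16.72 ± 0.04). The receptor gene Lrp3 was higher by 7.35 (SE 0.09, adjusted p = 1.8e-08), Hoxb13 by 7, the cotransporter gene Slc12a1 by 6.92, Atp6v1c2 by 6.31 and Tmem145 by 6.16. Here 13425 genes changed (64.7%), 7464 higher and 5961 lower, but cyclic loess scaling moved the share of changed genes that were higher from 55.6% to 45.3% and quantile scaling to 62.9%.

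Sertoli cell markers had 28 of 32 lower, 2 higher and 2 not called (30 called adjusted over the list alone; median -3.02, adjusted p = 2.2e-10, and adjusted p = 0.073 with an estimated correlation). Cst12 was lower by 9.16 and Defb19 by 8.52, Nr0b1 was higher by 4.05 and Vnn1 by 2.63, and Inha (0.45) was not called. Adult Sertoli genes had 15 of 17 lower and 2 higher (17 called adjusted over the list alone; median -2.98, adjusted p = 2.4e-06, and adjusted p = 0.089 with an estimated correlation), with Trf lower by 8.16, Ocln higher by 4.30 and Gja1 higher by 2.05. Germ cell genes had 19 of 20 lower (19 called adjusted over the list alone; median -6.98, adjusted p = 5.6e-10, and adjusted p = 0.20 with an estimated correlation), with Prm1 lower by 11.04 and Smcp by 10.30, and Ddx4 (-0.08) not called. Cell cycle genes had 22 of 25 higher and 3 not called (22 called adjusted over the list alone; median 1.69, adjusted p = 3.4e-07, and adjusted p = 0.19 with an estimated correlation), with Bub1b at 3.58, Kif11 at 3.27 and Cenpa at 2.54 and Rrm2 (0.22) not called.

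Fibroblast and mesenchymal genes were lower than even in mature Sertoli cells, with 25 of 29 lower, 2 higher and 2 not called (27 called adjusted over the list alone; median -2.42, adjusted p = 2.8e-09, and adjusted p = 0.19 with an estimated correlation). Fbln2 was lower by 8.72 and Dcn by 8.43, and Snai2 was higher by 0.55 and Zeb1 by 0.40. Interferon response genes had 21 of 22 lower and 1 not called (21 called adjusted over the list alone; median -4.22, adjusted p = 1.6e-09, and adjusted p = 0.27 with an estimated correlation), with Oas1a lower by 8.00 and Oasl2 by 7.28. Macrophage genes had 15 of 16 lower and 1 not called (15 called adjusted over the list alone; median -3.34, adjusted p = 4.9e-07, and adjusted p = 0.20 with an estimated correlation), with Tyrobp lower by 7.81 and C1qa by 6.19. Steroidogenic genes differed in sign between median (0.15) and mean (-0.34), with the test down at adjusted p = 0.96. Scarb1 was higher by 3.30 and Srd5a1 by 2.84, and Cyp11b1 was lower by 4.71.

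The last question was how Sertoli cells changed between fetal and adult life, in mature against immature Sertoli cells. Germ cell genes rose here, as did 12 of 16 macrophage genes, so RNA of other cells may contribute. The changes below are therefore those of the cultures and need not be those of Sertoli cells. Of the listed genes, 17 of 20 germ cell and 14 of 17 adult Sertoli genes rose one by one, and 23 of 25 cell cycle, 13 of 15 sterol synthesis and 25 of 29 fibroblast genes fell. Prm2 rose by 12.56 (SE 0.14, adjusted p = 1.3e-07), Prm1 by 12.12, Smcp by 10.25, the testis lactate dehydrogenase Ldhc by 10.01 (SE 0.58, 15.37 ± 1.48 in mature cells), Tnp2 by 9.58, Plaat5 by 9.06, Tcp11 by 8.88 and Gsg1 by 8.81. H19 fell by 9.32 (SE 0.30), Dlk1 by 8.25, Lrrc17 by 7.27, the glypican Gpc3 by 7.11, Itih5 by 6.84, Slc38a4 by 6.61, Pgm5 by 6.38 and B3gnt5 by 6.34 (SE 0.11 to 0.37). In total 12210 genes changed (58.9%), 6021 higher and 6189 lower, with 413 higher and 77 lower by 16-fold or more, and cyclic loess moved the higher share from 49.3% to 53.5% but quantile scaling to 42.7%.

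Of 32 Sertoli cell markers 24 rose, 3 fell and 5 were not called (28 called adjusted over the list alone; median 1.80, adjusted p = 3.2e-07, and adjusted p = 0.089 with an estimated correlation). Gata1 rose by 7.87, Etd by 6.35, Espn by 5.28 and Defb19 by 4.93 (SE 0.09 to 0.16), Fgf9 fell by 2.68, Amh by 1.76 and Gata4 by 0.47, and Inhbb (0.00) and Inha (0.14) were not called. Adult Sertoli genes had 14 of 17 higher, 1 lower and 2 not called (16 called adjusted over the list alone; median 2.62, adjusted p = 6.6e-06, and adjusted p = 0.094 with an estimated correlation), with Cldn11 up by 4.49. Fetal Sertoli genes rose too, with 11 of 16 higher, 3 lower and 2 not called (14 called adjusted over the list alone; median 1.41, adjusted p = 0.0054, and adjusted p = 0.18 with an estimated correlation). Aard rose by 3.85 and Cst9 by 3.65, and Krt8, a keratin of simple epithelia, fell by 1.99.

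Germ cell genes had 17 of 20 higher and 3 not called (18 called adjusted over the list alone; median 6.46, adjusted p = 5.7e-10, and adjusted p = 0.20 with an estimated correlation), with Tex14 (0.22) and the spermatogonial factor Zbtb16 (0.12) among those not called. Cell cycle genes had 23 of 25 lower and 2 not called (23 called adjusted over the list alone; median -1.58, adjusted p = 2.8e-09, and adjusted p = 0.19 with an estimated correlation), with the replication licensing genes Mcm2 and Mcm5 down by 2.98 and 2.79 and Ccna2 by 2.53. Sterol synthesis genes had 13 of 15 lower, 1 higher and 1 not called (15 called adjusted over the list alone; median -1.41, adjusted p = 0.00031, and adjusted p = 0.40 with an estimated correlation), with Cyp51 down by 2.47 and Sc5d up by 0.53. Fibroblast and mesenchymal genes had 25 of 29 lower, 3 higher and 1 not called (28 called adjusted over the list alone; median -1.61, adjusted p = 4.9e-07, and adjusted p = 0.20 with an estimated correlation). Thy1 fell by 5.50 and Col6a2 by 3.69, and S100a4 rose by 2.35, Fbln2 by 1.85 and Vim by 0.21.

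Macrophage genes had 12 of 16 higher, 1 lower and 3 not called (13 called adjusted over the list alone; median 1.56, adjusted p = 0.00065, and adjusted p = 0.29 with an estimated correlation), with Mrc1 up by 4.51, Lyz2 by 2.88 and Fcgr3 by 2.75 and Adgre1 down by 1.34. Peritubular myoid and smooth muscle genes had 6 of 12 lower and 6 not called (6 called adjusted over the list alone; median -0.67, adjusted p = 0.011, and adjusted p = 0.20 with an estimated correlation), with Myh11 down by 3.22, Lmod1 by 2.58 and Mylk by 2.15. Steroidogenic and Leydig genes were not called as a list (median -0.44, adjusted p = 0.28), but the androgen enzyme gene Hsd17b3 fell by 4.03 and Cyp11b1 rose by 5.24 (SE 0.13 and 0.18). Median, mean and test differed in sign for epithelial genes (-0.10, 0.12, down, adjusted p = 0.97), cartilage and bone genes (-0.11, 0.47, down, 0.92) and interferon response genes (-0.02, 0.28, up, 0.59).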

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

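Most alternatives were chosen before the data were examined; the 3-group fits without mature arrays, the fits without genes 8-fold higher in mature cells and the list tests under 75th percentile centring and cyclic loess were chosen after seeing them, as were the split of the MEF arrays and the 15 list results followed here. In the order NWD-MEF against MEF, immature and mature Sertoli against MEF, NWD-MEF against immature and mature Sertoli, and mature against immature Sertoli, genes changed numbered 11388, 8687, 12858, 11768, 13425 and 12210. Testing all named features one by one gave 17426, 13135, 19405, 17949, 20521 and 18516, and a log2 change of at least 1 gave 5592, 2965, 5865, 5494, 6771 and 5489, both by construction. Leaving out 1 array gave 9836 to 12507, 6376 to 10521, 10828 to 13324, 10040 to 13091, 11681 to 13924 and 10495 to 12730, the lone array being assumed to vary like the other groups. The remaining settings gave 9448 to 12547, 6018 to 10633, 10234 to 13065, 9532 to 13091, 11079 to 14190 and 9761 to 12448. Without the mature arrays 12507 genes changed between NWD-MEF and MEF, 10521 between immature Sertoli cells and MEF, and 13091 between NWD-MEF and immature cells. Leaving out the 741 genes higher in mature cells selects on the outcome, and the lower counts of 12170 (mature against MEF), 12783 (NWD-MEF against mature) and 11535 (mature against immature) partly follow from that. The code sets as a replicate block gave 11546, 8853, 12956, 11965, 13589 and 12416; deviations within the sets correlated at only 0.02 to 0.11, each from 2 numbers. The covariance with immature Sertoli cells stayed within 0.51 to 0.67 (0.56 to 0.59 leaving out 1 array) and that with mature ones within 0.93 to 1.24 (1.02 to 1.07); its fit to only the groups compared used the 3 groups it needs. The introduced genes have 1 feature each, and in the test of all named features none of their calls changed (Dmrt1 in NWD-MEF against MEF at adjusted p = 0.063, Nr5a1 in mature against immature cells at 0.036).

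With an estimated correlation the medians stay and the calls are lost for fibroblast and mesenchymal genes (-7.66, -1.52 in immature cells, -4.68 against immature cells), interferon response genes (-4.76), smooth muscle genes (-3.91), germ cell genes (7.12, 6.46 and -6.98), cell cycle genes (-1.58, mature against immature) and Sertoli cell markers (0.40, -1.73 and -3.02 in NWD-MEF against MEF, immature and mature cells, and 1.80 in mature against immature). Sertoli cell markers in NWD-MEF against MEF also lost their call with the mean over all features (median 0.31) and without mature replicate 1 or 2 (0.40; 0.33 to 0.46 leaving out any 1 array), and their median was 0.23 under cyclic loess and 0.63 under quantile scaling; the cause was not tested. Adjusted p of that list ran from 0.014 to 0.19, that of Dmrt1, NWD-MEF vs MEF from 0.011 to 0.30 and that of Nr5a1, mature Sertoli vs immature Sertoli from 0.0041 to 0.16. Over all lists and settings 96 calls were lost, 74 of them with an estimated correlation, 19 were gained and none reversed. Those 74 losses cannot be put down to correlation alone, because camera p-values also rose where the estimate lay below the preset 0.01. For adult Sertoli genes in immature Sertoli cells against MEF the estimate was -0.05, and camera p went from 2.9e-06 to 0.0073. Scaling flipped the sign of 10 (quantile), 2 (75th percentile) and 7 (cyclic loess) of 144 list medians, 0 of them called. Quantile scaling over named genes moved the median of all genes from 0.08 to 0.19 in NWD-MEF against mature cells. The dim filter left out 3322 genes, and without background flags changes from or to the lowest values are limited by signal over background.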

Other observations

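Each group also had genes apart from all 3 others. NWD-MEF had the most in total, 3751 higher and 2571 lower, of which 321 and 716 by 4-fold or more, so its 4-fold differences were mainly losses. Mature Sertoli cells had more lower genes and more genes higher by 4-fold, with 2952 higher and 3097 lower (873 and 102 by 4-fold). MEF had 1869 and 1240 (261 and 141), and immature Sertoli cells 1378 and 1269 (128 and 25). Hoxb13 stood at 13.43 in NWD-MEF against 6.55 in MEF, 5.33 in immature and 6.43 in mature Sertoli cells, and Cdkn2a at 14.99 against 14.02, 8.40 and 11.94.

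Tests of the Y chromosome, of the MEF label and of the array features, and the second germ cell list and imprinted gene set, were chosen after the results were seen. The first pattern is the rise of germ cell genes in mature over immature Sertoli cells, with a median of 6.46. Array scaling was not settled as the source: the lowest median over the scaling alternatives was 6.44, but the deposited columns already shared 1 distribution. Rescaling such columns could hardly move the median, as no list median moved by more than 0.53. RNA of germ cells in the mature Sertoli cultures is a candidate explanation: a second germ cell list of 24 other genes had a median of 3.47, with 18 higher by 2 or more and 21 called. Unequal germ cell RNA in the 2 mature arrays may go with this. That list differed by a median of 0.96 between them, and 21 of 24 genes were higher in array 1. The first list differed by a median of 0.48. The value of 0.96 lay outside -0.19 to 0.08, the range of 95% of 10000 random lists matched on mean level. Those lists drew genes whether or not they move together, so the range does not give the spread of a set that does. Only 1 pair of mature arrays was compared. Transcription of these genes by adult Sertoli cells themselves was not tested and stays open, and so does an effect of age.

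The second pattern is Eif2s3y near the lowest values in NWD-MEF (5.12, against 10.52 in MEF) while Xist stays at 8.64 against 8.72. Loss of dim signal in the NWD-MEF arrays could not be judged by the test made. It took 796 genes with a MEF mean like that of Eif2s3y, far above the 40th percentile of 5.67, so they were not dim. Only 5.4% of them (43 genes) lay below that percentile in NWD-MEF. Genes as bright as Eif2s3y in MEF thus mostly kept their signal. NWD-MEF cells without a Y chromosome, as in a culture from female embryos or after loss of the Y, cannot be told apart from a fall of this gene alone. Of 14 other Y genes only 1 was bright enough in MEF to inform, Uba1y at 10.54 in MEF and 10.37 in NWD-MEF. The sex of the embryos behind each culture may differ and is not given in the sources used here.

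The third pattern is that Nr5a1 and Wt1 fell in cells meant to carry them. For a MEF culture under the NWD-MEF label the steroidogenic test was set after the list was seen, so that test cannot decide. In it 46.2% of the steroidogenic list (6 of 13) was higher by 1 or more and called, beside 2822 of all 20738 genes. The list as a whole was not called (camera adjusted p = 0.16). Other values argue against a culture like that on the MEF arrays. Of 29 fibroblast and mesenchymal genes 28 fell in NWD-MEF and 1 rose, with a median of -7.66. The mean correlation of NWD-MEF with MEF was 0.904, against 0.9979 between the MEF arrays. A different uninfected culture was not measured. The factors also cannot be separated from a month of culture, as no such arm exists here. Features that read only the endogenous transcripts may explain it and cannot be told apart from silenced factors, because the most features for any of the 3 genes was 1. Withdrawal of doxycycline before collection, as the descriptions of both NWD-MEF arrays state, also stays open.

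A further hypothesis came from Meg3, which fell in NWD-MEF, H19, which fell in mature cells, and Dlk1, lower in NWD-MEF than in immature cells. It holds that imprinted genes may fall together in NWD-MEF against MEF, as a co-regulated fall of the imprinted gene network would have it. Of 15 imprinted genes not first seen, 0 rose, 10 fell and 5 were not called, with a median of -1.86 (limma camera p = 3.2e-05, and 0.011 with an estimated correlation). Both p-values are unadjusted, unlike those of the other lists. On the same scale camera with an estimated correlation gave 0.018 for fibroblast and 0.008 for smooth muscle genes, whose calls were lost after adjustment. Nnat fell by 7.52, Grb10 by 6.77, Asb4 by 2.78, Igf2r by 2.21 and Mest by 2.19, and Ndn (0.16), Gnas (-0.03), Impact (-0.09), Plagl1 (-0.22) and Phlda2 (-0.34) were not called. This shows only that the set fell, not that its members are regulated together. Such falls were not particular to NWD-MEF. In mature Sertoli cells Nnat read 7.65 and 8.44 against 12.98 and 13.01 in MEF, and Zim1 5.23 and 5.47 against 8.56 and 8.62. Peg10 went the other way there, at 8.94 and 8.84 against 6.41 and 6.47.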
